A study of Mus musculus with 6 samples.

How the data were processed

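RNA was taken from LSK cells of bone marrow, about 200 ng per the labels' protocols, and sequenced on an Illumina HiSeq instrument in 6 samples, 3 labelled Tgif1-/- and 3 labelled wild type. The submitters' processing notes name TopHat (read alignment) and Cuffdiff (group comparison), both without a version. The deposited table has 22381 genes and, per the file headers, gives 1 FPKM value (fragments counted against transcript length and the library's mapped total) for each group, computed by the authors. It also gives the authors' log2 fold change, test statistic, p-value and q-value for each gene, per the file headers. The header states which value column belongs to which group. The deposited fold change has the wild-type group on top and was turned round here. No column holds values of single samples, so the spread between samples, the depth per sample and differences between libraries could not be read. Low FPKM values did not show the steps of whole reads: of 1267 genes with both values above 0 and under 0.1 FPKM, at most 18 shared a ratio to 2 decimals of log2, so the depth is unknown.

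The deposited status marks 10730 genes as tested, 8455 as having too few reads to test, 3143 as failed, 43 as having too little data and 10 as having too much. Failed genes keep FPKM values while their deposited p-value is set to 1. The deposited q-values equal a Benjamini-Hochberg adjustment of the deposited p-values over the tested genes (all 10730 within 0.001), and the deposited p-values equal the normal two-sided value of the test statistic (all 10683 with values above 0 in both groups, within 0.001). The ratio of the log2 fold change to the test statistic was therefore used as the standard error implied by the deposited statistic. It is the error of the authors' model and not a spread measured here between samples. Its median fell from 0.73 in the tenth of tested genes with the lowest expression to 0.20 in the tenth with the highest. A group listed at 0 gives no finite fold, which held for 47 tested genes, 1 of them called.

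A gene was called where its status was tested and its deposited q was at or under 0.05. The genes named were fixed by rule before the data were examined: Tgif1, the 10 largest rises and 10 largest falls among called genes with at least 1 FPKM in both groups, and for each of 30 fixed lists up to 4 called members with at least 1 FPKM in a group or, with none called, the 2 members with the smallest p. Of the genes this rule selects, 2 are not reported here. Genes near Tgif1 and genes whose test failed were named after their values were seen. For each list the called members were set against other tested genes with Fisher's exact test, two-sided and adjusted by Benjamini-Hochberg over the 30 lists. The deposited p-values were also adjusted over the list alone. The list median was placed among medians of 10000 random lists matched on mean expression in 10 bins, which describes these group values and is not a test across samples. The lists hold 618 genes of the table, 411 tested and 129 failed, and 29 genes stand in more than 1 list. A symbol on more than 1 line was taken from the line with the higher mean FPKM.

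The processing notes name hg19, a human build, while all 22381 identifiers are mouse identifiers. Of 20781 identifiers found in GENCODE M21 (GRCm38), 173 had the same position and 8704 the same length, so the positions belong to another mouse build that is not given in the sources used here. Starts are printed counting from 1. Many positions are shared blocks, the largest holding 75 genes, so neighbouring genes may have been quantified together, and antisense or overlapping genes cannot be told apart where strand is not stated.

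Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. The tests were run on simulated data first: log2 noise with the implied standard errors of 10683 genes. In these data 200 genes with a mean of at least 1 FPKM were changed by known folds. The test recovered 25.4% of genes changed by 1.5-fold, 58.2% changed by 2-fold and 92.4% changed by 4-fold, with 4 false calls. With the error floor the same figures were 8.96%, 49.3% and 90.9%. The implied errors made both the noise and the test, so few false calls cannot show that those errors are right. Of 100 simulated lists with no change and with noise independent between genes, 8 fell outside the central 95% of random lists. Alternatives fixed before the data were examined were other q thresholds (0.01 and 0.1), minimum folds (1.5 and 2), minimum FPKM values (1 and 5), centring on the median of tested genes, 1 line per symbol, pseudocounts of 0.1 and 1 for log2 ratios, and random lists not matched. Alternatives added after seeing the data were a floor on the implied standard error at the median of genes in the same of 20 expression bins, leaving out genes within 5 Mb of Tgif1, and random lists matched on expression and exon length.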

Results

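Gene expression was measured by RNA sequencing in LSK cells, the bone marrow fraction that lacks mature lineage markers, carries Sca-1 and c-Kit, and holds the blood-forming stem cells and early multipotent progenitors. The cells came from C57BL/6 mice aged 8 to 12 weeks. By the labels, 3 samples came from mice lacking Tgif1, a homeodomain repressor that acts on TGF-beta and retinoic acid signalling, and 3 from wild-type mice. Nothing in the labels says that the 3 samples of a group came from separate animals, so any spread between them may be technical. The Cuffdiff p-values below rest on the error of the authors' model. Those of Fisher's exact test count genes and cover no spread between samples. The table used here gives 1 FPKM value per group, with no SD and no value per sample, and the sequencing depth is unknown. The series title names quiescence and self-renewal of blood stem cells, and the comparison asks which genes and pathways differ between the groups. Pairs of FPKM values are given with the group labelled Tgif1-/- first, and log2 ratios are the group labelled Tgif1-/- over the group labelled wild type.

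Tgif1 itself (ENSMUSG00000047407, chromosome 17, positions 71193545 to 71202886 in the table) was not lower in the group labelled Tgif1-/-. Its authors' values were 88.6 FPKM in that group and 71.5 FPKM in the group labelled wild type, a log2 ratio of 0.31. The authors' deposited table marks the test of this gene as failed, so no error or p-value goes with it. The value of the targeted gene therefore does not bear out the label and cannot refute it, and each direction below is a direction between groups as labelled. The part of the gene removed in these mice is not given in the sources used here, and a value over the whole gene does not show whether a deleted part is missing. Positions are those of the table, whose mouse build is not named in the sources used here and is not GRCm38.

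In the group labelled Tgif1-/-, 4 of 11 tested markers of mast cells and basophils were called higher, 4 of 13 tested B cell markers were called lower, and 4 genes lying within 5 Mb of Tgif1 were called higher. In the authors' deposited table, 71 of 10730 tested genes had a q at or under 0.05 in the Cuffdiff test, 31 of them higher and 40 lower in the group labelled Tgif1-/-. Of these, 17 were higher and 17 lower by at least 2-fold, and 29 differed by less than 1.5-fold. With each gene's error set to at least the median error of genes at like expression, a choice made after the data were seen, 22 genes were called, 12 higher and 10 lower, and none of the 29 small changes was among them. Such a floor leaves changes under 1.5-fold little room to be called, so their loss follows largely from the rule. The tests of 3143 genes failed and are not part of these counts. They include 24.2% of the 12452 genes with at least 1 FPKM in a group.

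Among called genes with at least 1 FPKM in both groups, Ehd3, which encodes an endocytic recycling protein, rose the most, from 1.29 FPKM in the group labelled wild type to 8.10 FPKM in the group labelled Tgif1-/-. Its log2 ratio was 2.65 with an implied standard error of 0.36, and its q in the authors' deposited table was 6.71e-10. With a pseudocount of 1 the log2 ratio of Ehd3 was 1.99. Several other genes were those of mast cells, basophils and eosinophils. Prg2, eosinophil major basic protein, stood at 61.8 and 20.9 FPKM. The serine proteases Prss34 and Mcpt8 stood at 151 and 51.8 FPKM and at 77.2 and 28.0 FPKM. Ms4a2, the beta chain of the high-affinity IgE receptor, stood at 15.4 and 6.12 FPKM. Alox5, which starts leukotriene synthesis, stood at 8.55 and 3.40 FPKM. The MHC class II gene H2-Eb1 stood at 21.5 and 9.37 FPKM, Csrp3, a LIM protein of muscle, at 3.30 and 1.24 FPKM, Cdh1, E-cadherin, at 3.96 and 1.60 FPKM, and Camk2b, a calmodulin-dependent kinase subunit, at 3.87 and 1.74 FPKM. Across these 10 genes the log2 ratio ran from 1.16 to 2.65, the implied standard error from 0.12 to 0.36, and q in the authors' deposited table reached at most 0.0481. Prss34 and Mcpt8 belong to a family of related proteases and H2-Eb1 to a family of related class II genes, so reads shared with relatives leave their values uncertain.

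The largest falls included genes of the B cell lineage. Ebf1, a transcription factor that sets B lineage identity, fell from 13.7 to 3.13 FPKM, a log2 ratio of -2.13 with an implied standard error of 0.50 and a q of 0.00684 in the authors' deposited table. Igll1, part of the surrogate light chain of the pre-B cell receptor, fell from 40.9 to 12.7 FPKM. Blnk, an adaptor of B cell receptor signalling, fell from 11.8 to 4.24 FPKM, Cd79a, a signalling chain of that receptor, from 13.7 to 5.16 FPKM, and Siglecg, a lectin of B cells, from 5.30 to 1.96 FPKM. The other five genes were Gfra2, a receptor for neurturin, at 1.54 and 3.96 FPKM, AA467197 at 2.53 and 6.39 FPKM, Lef1, a transcription factor of the Wnt pathway, at 1.41 and 3.02 FPKM, Emp1 at 8.47 and 17.6 FPKM, and Hmga2, a chromatin architectural protein, at 10.2 and 19.4 FPKM. Across the 10 genes the log2 ratio ran from -2.13 to -0.93, the implied standard error from 0.16 to 0.50, and q in the authors' deposited table reached at most 0.0323. With the error floor named above, adjusted p rose to 0.0814 for Siglecg, 0.0964 for Gfra2, 1.00 for Lef1, 0.432 for Camk2b, 0.151 for Cdh1 and 0.268 for Csrp3, which ended those 6 calls.

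Genes around Tgif1 on chromosome 17 stood out, a feature chosen after the values were seen. Dlgap1, a postsynaptic scaffold gene whose listed end at position 71170753 lies 22.8 kb before Tgif1, was at 9.12 FPKM in the group labelled Tgif1-/- and 0.0974 FPKM in the group labelled wild type, a log2 ratio of 6.55 with an implied standard error of 0.59. The low wild-type value makes that ratio uncertain, and it was 5.55 with a pseudocount of 0.1 and 3.21 with a pseudocount of 1. Myom1, a muscle sarcomere gene at positions 71368861 to 71476196, was at 2.89 and 0.454 FPKM, Clip4 at positions 72119042 to 72207691 was at 0.780 and 0.173 FPKM, and Ehd3 lies at positions 74154181 to 74181433. With a pseudocount of 1 the log2 ratio went from 2.67 to 1.42 for Myom1 and from 2.17 to 0.60 for Clip4. Other neighbours had lower values in the group labelled Tgif1-/- without being called, C030034I22Rik at 0.457 and 1.73 FPKM (p = 0.00237 in the authors' deposited table) and Epb4.1l3, whose test failed, at 3.57 and 7.40 FPKM. Within 5 Mb of Tgif1, 4 of 34 tested genes were called, against 67 of 10696 elsewhere (two-sided Fisher's exact test, p = 7.03e-05, on a feature first noticed in these values). None of 10162 windows of that width, each centred on a tested gene of another chromosome, held as many called genes, and the most in any of them was 3. Windows of neighbouring genes overlap, so they are not independent and their number overstates how rare this is. With the error floor the adjusted p of Clip4 rose to 0.873.

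**Figure D1:**
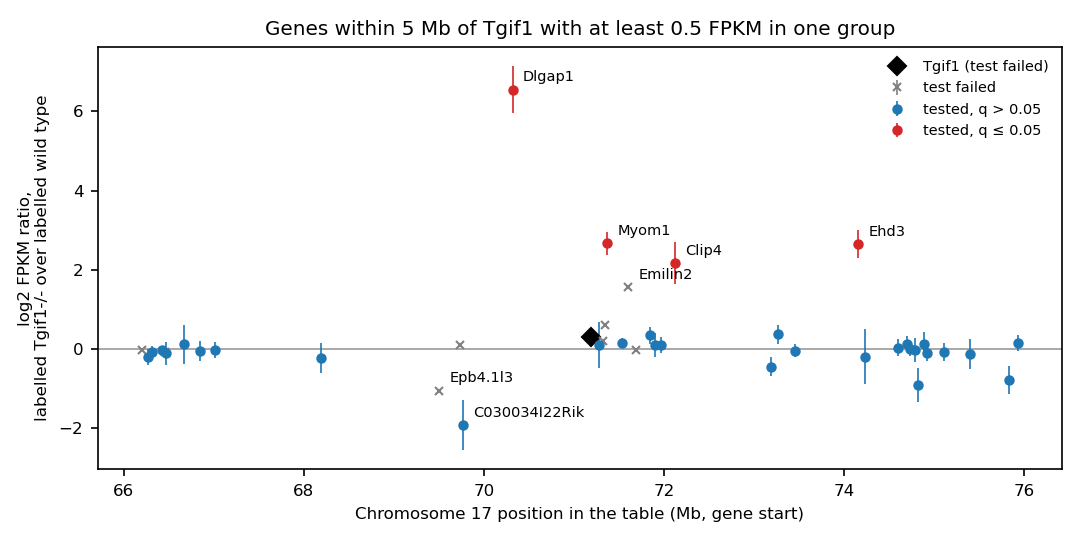
Log2 FPKM ratio (y axis, group labelled Tgif1-/- over group labelled wild type) against gene start on chromosome 17 (x axis, Mb in the table's own coordinates), for genes with at least 0.5 FPKM in a group; bars are the standard error implied by the deposited test statistic, and crosses are genes whose test failed. Dlgap1, Myom1, Clip4 and Ehd3 lie above 2 on the log2 scale while most neighbours lie near 0.

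Of the 30 gene lists fixed before the data were examined, the mast cell and basophil list and the B cell list held a larger share of called genes than the other tested genes. All 11 tested mast cell and basophil markers were higher in the group labelled Tgif1-/-, and 4 of them were called (Prss34, Mcpt8, Ms4a2 and Cpa3, a mast cell carboxypeptidase at 115 and 52.4 FPKM). Adjusted over the list alone, 5 were higher, and Fisher's exact test gave an adjusted p of 1.68e-05. The list's median log2 ratio of 0.84 lay above those of all 10000 random lists matched on expression. Of 13 tested B cell markers, 10 were lower and 3 higher, and 4 were called, all 4 lower (Ebf1, Igll1, Blnk and Cd79a), with 7 lower when adjusted over the list alone and an adjusted p of 1.80e-05 by Fisher's exact test. Its median of -1.26 lay below those of all the random lists. The 3 higher ones were Cd79b at 27.8 and 27.6 FPKM, Igj at 34.8 and 33.0 FPKM and Cr2 at 1.38 and 1.24 FPKM, none of them called. Both lists kept an adjusted p at or under 0.05 in each alternative run for this test.

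**Figure D2:**
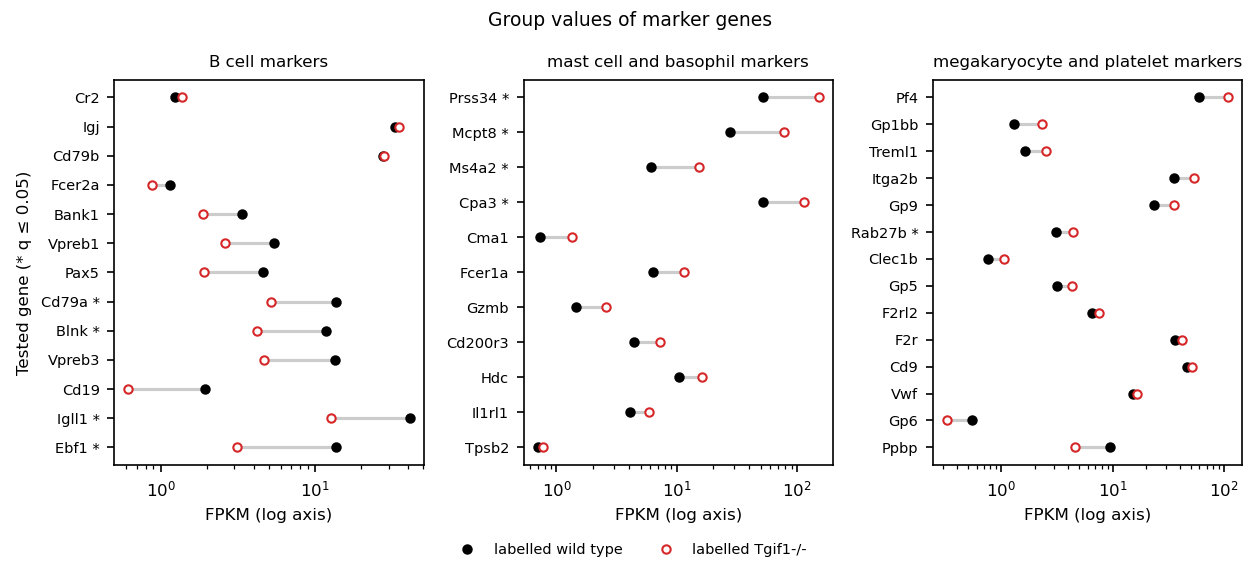
FPKM (x axes, log scale) of each tested B cell, mast cell and basophil, and megakaryocyte marker in the group labelled wild type (black) and the group labelled Tgif1-/- (open red); each point is the authors' group value with no error given, and stars mark a q at or under 0.05. The 4 starred B cell markers lie to the left of their wild-type points and the 4 starred mast cell and basophil markers to the right.

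Medians of other blood cell lists lay on both sides of 0, with few or no called members. Of 14 tested megakaryocyte markers, 12 were higher and 1 was called, Rab27b, a vesicle transport GTPase at 4.42 and 3.10 FPKM (q 0.0141 in the authors' deposited table, and 1.00 with the error floor). Adjusted over the list alone, 3 were higher (Rab27b, Pf4 and Itga2b) and 1 was lower (Ppbp), and the list median was 0.47, above all random lists. It was 0.21 (percentile 99.98) over members with at least 5 FPKM in a group and 0.29 with a pseudocount of 1. In the erythroid list 14 of 18 tested markers were higher and none was called by Cuffdiff. At an unadjusted p under 0.05 there was 1, carbonic anhydrase gene Car1 at 281 and 187 FPKM (p = 0.0014 in the authors' deposited table), which was also the 1 that passed over the list alone. Sphk1 was at 3.36 and 2.45 FPKM, and the list median was 0.35, above all random lists. Of 10 tested dendritic cell and MHC class II markers, H2-Eb1 was called, 2 were higher when adjusted over the list alone, and the median of 0.20 lay at percentile 99.6 of random lists, or 0.09 at percentile 93.1 over members with at least 5 FPKM in a group. In the neutrophil and granule list none of 15 tested markers was called by Cuffdiff, 6 were lower at an unadjusted p under 0.05 and 2 were lower when adjusted over the list alone, Ltf at 0.353 and 1.33 FPKM and Ngp at 3.47 and 8.19 FPKM. Its median of -0.80 lay below all random lists, and was -0.35 at percentile 0.02 over members with at least 5 FPKM in a group. No monocyte and macrophage marker of 12 was called by Cuffdiff or had an unadjusted p under 0.05, with Irf8 at 35.3 and 41.5 FPKM, C1qa at 0.833 and 0.405 FPKM, and the median of 0.01 at percentile 74.8. Over members with at least 5 FPKM in a group the monocyte median was -0.19, at percentile 0.5 and outside the random range. T and NK cell markers gave 0 calls of 14 and 2 at an unadjusted p under 0.05, among them Klrd1 at 3.12 and 5.27 FPKM, with a median of 0.03 at percentile 84.9, or -0.05 and -0.10 over members with at least 1 and 5 FPKM in a group, inside the random range. Stromal and endothelial markers gave 0 calls of 6 and 2 at an unadjusted p under 0.05, Fn1 at 0.467 and 1.07 FPKM and Bgn at 5.93 and 11.9 FPKM, both lower over the list alone, with a median of 0.00 at percentile 70.5, or -0.08 over members with at least 1 FPKM in a group.

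Lymphoid priming genes, which mark the first lymphoid steps of multipotent progenitors, held no called gene among 8 tested, of which 6 were lower and 2 higher. At an unadjusted p under 0.05, 3 were lower: Dntt, terminal deoxynucleotidyl transferase, at 302 and 437 FPKM (p = 0.00186 in the authors' deposited table), Il7r, the interleukin-7 receptor, at 8.84 and 13.6 FPKM, and Tcf3 at 66.0 and 83.0 FPKM. Dntt alone passed over the list alone, and the list median of -0.16 lay at percentile 0.2 of expression-matched lists and at percentile 7.15 of lists not matched. The tests of another 9 members failed. The retinoic acid list, which bears on a known Tgif1 pathway, held no call by Cuffdiff among 11 tested genes and 2 lower at an unadjusted p under 0.05, Rara at 10.2 and 12.9 FPKM and Cyp26b1 at 0.197 and 0.400 FPKM. Its median of -0.27 lay at percentile 1.33, or -0.19 at percentile 4.74, inside the random range, over members with at least 5 FPKM in a group. In the canonical Wnt list 18 of 19 tested genes were lower, Lef1 was called and passed over the list alone, 2 were lower at an unadjusted p under 0.05, and the median of -0.18 lay at percentile 1.39. That median moved inside the random range over members with at least 1 FPKM in a group (-0.14, percentile 4.01) and with at least 5 (-0.12, percentile 3.81). Fisher's exact test of that list gave an adjusted p of 0.712.

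The lists closest to the title's subject held no called gene, but members whose test failed could not be called. Tests failed for 5 quiescence regulators, 8 stem cell identity genes, 3 TGF-beta and BMP targets and 5 pathway components. They also failed for 3 Notch, 4 Hox, 6 niche adhesion and 7 chromatin genes. Of 20 tested quiescence regulators, 2 were lower at an unadjusted p under 0.05 in the Cuffdiff test, Egr1 at 10.9 and 14.5 FPKM and Cdkn1a, the cell cycle inhibitor p21, at 34.3 and 47.3 FPKM, with a list median of -0.09 at percentile 11.8. Of 24 tested stem cell identity genes, 1 was higher, Trim47 at 15.2 and 10.7 FPKM, and 1 lower, Erg at 81.6 and 93.3 FPKM, at that level, with a median of 0.01 at percentile 85.0. Over members with at least 5 FPKM in a group the identity median was 0.06, at percentile 98.7 and outside the random range. TGF-beta and BMP target genes (12 tested) and pathway components (14 tested) had none at an unadjusted p under 0.05, with medians of -0.13 and -0.10 at percentiles 22.9 and 7.72. The median of the targets was -0.05 over members with at least 1 FPKM in a group and -0.06 with a pseudocount of 1. Their smallest p-values belonged to Ski, at 15.5 and 17.2 FPKM, Tgfbi, at 4.79 and 5.50 FPKM, Zfyve9, at 0.357 and 0.627 FPKM, and Acvr2b, at 0.959 and 1.52 FPKM. The Notch list (9 tested) had none at that level, with Numb at 19.0 and 21.7 FPKM, Notch4 at 2.40 and 1.23 FPKM and a median of -0.06 at percentile 44.4. Hox genes (13 tested) had 1 lower, Hoxa10 at 6.39 and 8.28 FPKM, with Hoxa9 at 30.3 and 36.8 FPKM and a median of -0.12 at percentile 13.5, or -0.18 over members with at least 5 FPKM in a group and -0.07 with a pseudocount of 1. Niche adhesion genes (14 tested) had 2 higher, Itga2b at 54.0 and 35.2 FPKM, which passed over the list alone, and Itgb1 at 104 and 84.1 FPKM, with a median of 0.07 at percentile 96.1, or 97.6 among lists also matched on exon length, just outside the random range. Chromatin regulators (19 tested) had 2 lower, Tet3 at 30.1 and 36.3 FPKM and Dnmt3b at 44.8 and 52.3 FPKM, with a median of -0.06 at percentile 7.43.

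Cell cycle and metabolic lists held no called gene in the Cuffdiff test, but members whose test failed could not be called. Tests failed for 12 mitotic, 9 replication, 9 glycolysis, 8 oxidative phosphorylation, 11 ribosomal protein and 9 interferon-response genes. Mitotic genes (17 tested), replication genes (21 tested), glycolysis genes (10 tested), oxidative phosphorylation genes (20 tested) and cytosolic ribosomal proteins (17 tested) had 0 at an unadjusted p under 0.05, with medians of 0.02, -0.03, 0.00, 0.06 and 0.03 at percentiles 76.8, 21.7, 56.5, 97.2 and 76.8. Their smallest p-values belonged to Ndc80 at 34.7 and 27.4 FPKM, Aurka at 23.1 and 25.7 FPKM, Mcm10 at 55.6 and 44.9 FPKM, Lig1 at 271 and 285 FPKM, Pfkfb3 at 16.9 and 14.5 FPKM, Pgam1 at 215 and 186 FPKM, Ndufa9 at 78.6 and 69.0 FPKM, Sdha at 387 and 341 FPKM, Rps6 at 2718 and 2435 FPKM, and Rpl22 at 2235 and 2002 FPKM. Cyclin D, CDK and inhibitor genes (12 tested) had 1 lower at that level, Cdkn1a, with Rbl2 at 69.5 and 77.5 FPKM and a median of -0.07 at percentile 13.6. Of 18 p53 targets none was called, and 2 had an unadjusted p under 0.05, Cdkn1a, which was lower, and Fas, a death receptor at 2.07 and 0.338 FPKM (p = 0.000659 in the authors' deposited table), the 1 that passed over the list alone, with a median of 0.00 at percentile 76.0. Interferon-response genes (17 tested) had 0 at that level, with Iigp1 at 7.77 and 6.11 FPKM and a median of 0.15 at percentile 99.9. Immediate early genes (21 tested) had 3 lower, with Egr1 as above, Fos at 7.66 and 11.2 FPKM and a median of -0.11 at percentile 10.4. The 4 tested sex-linked genes had 0, with the Y-linked genes Uty at 9.09 and 11.8 FPKM and Kdm5d at 6.06 and 6.37 FPKM, and a median of -0.11 at percentile 30.4.

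**Figure D3:**
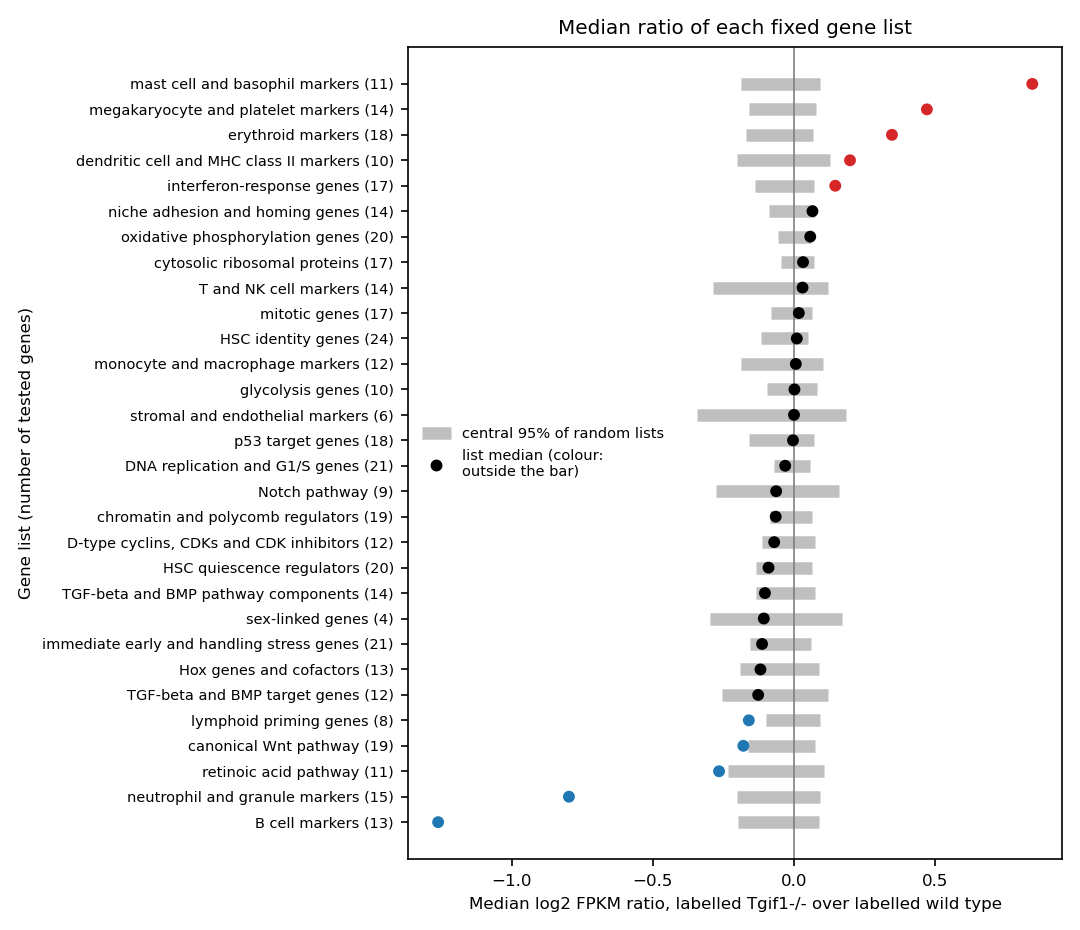
Median log2 FPKM ratio (x axis, group labelled Tgif1-/- over group labelled wild type) of the tested genes of each of 30 lists (y axis, with the number tested), beside the central 95% of medians of 10000 random lists matched on mean expression (grey bars). The medians of 10 lists lie outside their bars, where a nominal 1.5 would by chance if the genes of a list were independent draws. In simulation 8 of 100 lists with no change fell outside, but its noise was independent between genes, so correlated markers were not covered. The B cell list lies lowest at -1.26 and the mast cell and basophil list highest at 0.84.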

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

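Genes whose test failed are outside the calls of the report, and 2 of them had at least 5 FPKM and were at least 2-fold higher in the group labelled Tgif1-/-, a rule chosen after the values were seen. Emilin2, an extracellular glycoprotein gene near Tgif1 on chromosome 17, was at 15.5 FPKM against 5.26 FPKM in the group labelled wild type. Slc11a2, a divalent metal transporter, was at 31.1 FPKM against 7.54 FPKM. Of 2776 failed genes with at least 5 FPKM in a group, another 7 were at least 2-fold lower. They were the line ENSMUSG00000090649, listed as Psmd14, at 1.59 and 8.58 FPKM, Gm10197 at 6.30 and 15.7 FPKM, and Ces3a at 4.66 and 11.3 FPKM. The rest were Chi3l3 at 8.13 and 18.7 FPKM, Itgb5 at 8.71 and 18.8 FPKM, S100a9 at 18.9 and 39.2 FPKM, and Epb4.1l3 at 3.57 and 7.40 FPKM. No error goes with any of these values.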

How the results depend on the processing

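The error floor, the calls without genes near Tgif1 and the lists matched on exon length were chosen after seeing the data. Against 71 calls (31 higher and 40 lower in the group labelled Tgif1-/-), a q of 0.01 gave 39 (19 and 20), a 1.5-fold minimum 42 (18 and 24), a 2-fold minimum 34 (17 and 17) and the error floor 22 (12 and 10), while a q of 0.1 gave 61 lower genes. The drops at a stricter q or fold follow from the rule itself. Under the error floor the 29 calls below 1.5-fold all ended because their implied standard errors were small, with a median of 0.06 against 0.20 among genes of like expression. The other settings left the counts within 1.5 times, and centring gave 36 higher of 68. Without genes within 5 Mb of Tgif1 there were 67. The Tgif1 ratio was 0.31 with both pseudocounts. The number of lists with an adjusted p at or under 0.05 was 2, or 3 at a q of 0.1. Of 209 list medians under other settings, 201 stayed on their side of the random range, 5 moved inside it (retinoic acid and dendritic cell lists at a minimum of 5 FPKM, Wnt at 1 and at 5 FPKM, lymphoid priming without matching) and 3 moved outside (stem cell identity and monocyte lists at 5 FPKM, niche adhesion with length matching). Of named genes, 8 lost their call with the error floor, and 16 with an implied error moved beyond it with a pseudocount, Dlgap1 the furthest (6.55 to 3.21). No paired analysis was possible because the table holds 1 value per group and the replicate numbers are not shared between groups. For the same reason leaving out each replicate, a replicate block and other splits of the samples were not run.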

Other observations

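Several further genes of the lymphoid branch, picked after their values were seen, were not called. Notch1, which directs early T cell fate, was at 78.1 and 108 FPKM, Rag1 and Rag2, which cut antigen receptor genes, were at 1.08 and 2.11 FPKM and at 11.2 and 19.2 FPKM, and Ikzf1 was at 236 and 295 FPKM, all with a failed test. Immunoglobulin segments went both ways, with Igkv4-71 at 16.5 and 57.8 FPKM and Iglc3 at 4.93 and 0.764 FPKM, and near-identical segments leave both uncertain. Members of the dendritic cell and MHC class II list included Cd74 at 104 and 74.6 FPKM, H2-Aa at 105 and 65.4 FPKM and H2-Ab1 at 114 and 76.0 FPKM. Of the 10 tested members of that list 7 were higher and 3 lower, and the tests of another 4 failed. All tests in the paragraphs below were chosen after the results were seen.

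Tgif1 was not lower in the group labelled Tgif1-/-. Whether the failed test gave a wrong value is not settled: 0% of 686 failed genes of 50 to 150 FPKM lay as far from their median ratio as Tgif1 lies from a 2-fold fall. The true ratios of those genes are unknown, so this shows a narrow scatter but not that the Tgif1 value is right. If the Tgif1 values hold, swapped group columns with most of the transcript lost in the other group are argued against, since the log2 ratio of the lower over the higher value was only -0.31. That figure restates the ratio already seen. An allele that keeps part of the transcript may explain the whole-gene ratio of 0.31, and cannot be told apart from other causes because no value per exon was used here. A swap of columns with the transcript kept also stays open.

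The called genes near Tgif1 may reflect DNA of another strain kept around the targeted gene, but this cannot be told apart from other causes. Of genes with at least 1 FPKM in a group, 15.4% of 39 within 5 Mb differed by 2-fold or more (4 higher and 2 lower) against 1.68% of 12413 elsewhere. Without called genes on either side it was 8.33% of 36 (Emilin2, C030034I22Rik and Epb4.1l3) against 1.49% of 12351 (two-sided Fisher's exact test, p = 0.0168). These genes had been seen before the test was set, an earlier version of which left out some of them and was set aside, and an effect of Tgif1 loss on its neighbours would give the same excess. Transcription running on from Tgif1 to Myom1, Clip4 and Ehd3 is argued against, since Tgif1 is on the minus strand in GENCODE M21 and 0 of these 3 genes lie in the direction of its transcription. Dlgap1 does lie in that direction at 22.8 kb but is on the plus strand, so run-on into it would be antisense. Such run-on cannot be told apart from the rest because no values between genes were used here. An effect of Tgif1 loss on its neighbours has the same grouping as the genotype and stays open.

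Whether a lower share of LSK cells gave the higher mast cell and basophil markers and lower B cell markers is open. It would raise both lists only if their transcripts came from other cells, which was not tested here. The list medians differed by 2.11 on the log2 scale (95% interval 1.21 to 2.65 from resampling the genes of each list, which are not independent replicates). The lists were picked as the highest and lowest of 30, so a wide gap was to be foreseen and cannot decide this. More mast cells or basophils in the sort and a shift of priming within LSK cells cannot be told apart, since both would give the 11 of 11 higher markers, led by Prss34 and Cpa3 at 151 and 115 FPKM, of which 9 had at least 1 FPKM in the group labelled wild type. The Lineage, Sca-1 and c-Kit gates would remove most mature B cells, but how far they remove mast cells and basophils is not shown by any value used here. Against fewer mature B cells in the sort stand Ms4a1 and Cd22, at 0.0594 and 0.191 FPKM in the group labelled wild type where Cd79a was lower by 8.51 FPKM, but Fcer2a at 1.15 and Cr2 at 1.24 FPKM exceed the bound set at 0.851 FPKM, which the median of the 4 genes (0.670 FPKM) does not reach. The test of the highest gene therefore left this open. Of the 4 genes, 3 were higher in the group labelled Tgif1-/-, but Ms4a1 and Cd22 had too few reads to test. The third, Cr2, was at 1.38 and 1.24 FPKM and was not called. An earlier version with 7 genes, whose 5 members with at least 1 FPKM had a median log2 ratio of 0.59, excluded fewer mature B cells and was set aside because the high baseline of class II genes would hide a small share.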
